A study of Mus musculus with 4 samples.

How the data were processed

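RNA was measured by sequencing in 4 libraries of mouse T helper 17 (Th17) cultures, 2 from wild-type (WT) mice and 2 from mice of the genotype given as Setd2-CD4 cre. Per the labels' protocols, total RNA was taken with TRIzol from naive splenic CD4+ T cells of C57BL/6 mice after 3 days in Th17 conditions, and libraries were made and sequenced by a commercial service on an Illumina HiSeq instrument. Groups were taken from the sample titles, with the numbers in the titles as replicate names (WT 13 and 15, Setd2-CD4 cre 22 and 24). The sample titled 15 has a cell type label that begins with 14, and the title was followed. The groups share no number, so no pairing was fitted.

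The authors deposited whole-number read counts per gene and, beside them, FPKM values, per the file headers. Bowtie2 and RSEM are named in the submitters' processing notes, as are GRCm38.p6 and mm10, without versions or roles. RSEM gives estimates that need not be whole, and whether the deposited counts were rounded is not stated. How reads shared between genes were counted, whether strand was used and which gene models were taken are not given in the sources used here. Antisense genes, overlapping genes and near-identical copies such as Hspa1a and Hspa1b are therefore uncertain. The deposited FPKM followed from the count, the library's summed count and 1 whole-number length per gene, with a largest difference of 0.0674% over the 64572 values checked. All 34745 gene rows carried an identifier, of which 34267 were found in GENCODE release M21 (GRCm38), the source of coordinates and gene classes. No per-sample column was left unused.

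Total counts were 12518415 and 12414098 for WT 13 and 15, and 11007343 and 11322621 for Setd2-CD4 cre 22 and 24. A count of 0 in 1 library allows up to 3 counts, which is 0.240, 0.242, 0.273 and 0.265 CPM (counts scaled to a library of 1e6) in the same order. These floors and all counting intervals cover counting error only. The replicates of each genotype differed by more than counting noise, with a chi-square per degree of freedom of 8.27 over 13814 genes in WT and 17.4 over 13600 genes in Setd2-CD4 cre, so no library was treated as a copy of another. The labels do not say that the libraries came from separate animals or cultures. The p-values measure only the spread between these samples, which may be technical.

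The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter by genotype, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment over the 12927 genes tested, with a threshold of 0.05. The factors were 1.05, 1.06, 0.934 and 0.964 for WT 13, WT 15, Setd2-CD4 cre 22 and Setd2-CD4 cre 24. Values per gene are TMM-scaled CPM, given as mean ± SD over 2 libraries, and fold changes are Setd2-CD4 cre over WT. With 2 libraries against 2, an exact two-sided permutation test of 1 gene cannot give a p below 0.333, so single genes were tested only in the model across genes.

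Gene lists of T helper programs, metabolism, stress, proliferation, chromatin and other cell types were fixed by symbol before the data were examined, as were the tests, the rule for named genes and most alternative settings. Of the listed symbols, 876 matched a gene directly, 26 through a synonym and 1 through a repeated symbol, and 17 matched none. Lists with at least 5 tested genes (38 of 42) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over those lists. The same lists were tested with an estimated correlation and with fry. The 294 pathways that the deposited table names for 10 to 300 tested genes were tested likewise. Named genes are Setd2 and Lpcat4 and the 12 largest rises and 12 largest falls among genes past the threshold that had a mean of at least 5 CPM in the higher genotype, no overlap between genotypes and no predicted-gene name. For each list described, the 2 to 4 members with the smallest p-values are also named, with Il17a, Il17f, Il22, Il23r, Rora and Foxp3 always. Some genes that this rule selects are not reported here. Genes named outside this rule are said to be so.

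The tests were tried on simulated counts with WT means for both genotypes, real library sizes and dispersions, and 200 of 12927 genes changed. In the real data 30.7% of tested genes were called. Recovery and the share of false calls depend on how many genes change, so the simulated values need not hold for the real data. With gene-wise dispersions, edgeR recovered 8 of 67 genes changed 1.5-fold, 46 of 67 changed 2-fold and 57 of 66 changed 4-fold, and 24 of its 135 calls were unchanged genes (17.8%). The share of false calls was therefore above the nominal 5%. The same share was 21 of 127 for DESeq2, 19 of 115 for limma-voom and 14 of 111 for limma-trend. A simulation with trended dispersions, added after that result was seen, gave 4 of 118 false calls (3.39%) with edgeR. A simulated raised list was called by camera with the preset correlation and by fry but was missed with the estimated correlation, and 0 of 37 unchanged lists was called by any of them.

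Alternatives were DESeq2's size factors, upper-quartile factors, library totals alone, no filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a non-robust fit, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), omission of each library in turn and omission of the 50 most abundant genes. Stricter thresholds were an adjusted p under 0.01 and a change of at least 2-fold. Cyclic loess scaling, a fit of protein-coding genes alone and a gamma-delta T cell list without Blk were added after the data were seen. No outlier test was made, since no group held 4 samples, and other splits of the 4 libraries were not counted, since 2 against 2 allows 3 in all.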

Results

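Gene expression was measured in Th17 cells, the CD4+ T cell subset that makes interleukin 17, after 3 days of culture from naive splenic CD4+ T cells. Wild-type (WT) cultures gave 2 libraries, replicates 13 and 15, and Setd2-CD4 cre cultures gave 2, replicates 22 and 24. Setd2 encodes the methyltransferase that places the trimethyl mark on lysine 36 of histone H3, and Cre expressed from Cd4 sequences is a common means of altering genes in T cells. The exons removed are not given in the sources used here. Libraries held 11007343 to 12518415 counts over 15882 to 16307 genes with at least 1 count, and the most abundant gene, mt-Co1, took 2.74 to 3.20% of each. The first principal component separated the genotypes and held 74.3% of the variance, and the second held 16.5%, with the Setd2-CD4 cre replicates at its ends.

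The comparison of genotypes addressed how Setd2 shapes the Th17 transcriptome, with Lpcat4, an enzyme that adds acyl chains to lysophospholipids, named in the title of the series. In Setd2-CD4 cre cultures Il17a, the signature cytokine gene of these cells, was 3.17-fold higher and Il23r, the receptor gene for the cytokine that sustains them, was 9.04-fold higher. Tnf, a proinflammatory cytokine gene, was 5.71-fold lower and Lpcat4 was 2.02-fold lower. As groups, genes of DNA replication lay lower than other genes and genes of the cytosolic ribosome, the unfolded protein response and the B cell lineage lay higher. These differences passed by camera with a preset correlation and not with an estimated correlation (adjusted p = 0.862 to 0.987). Il17f and Il22, which encode 2 other Th17 cytokines, did not pass the test.

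Setd2 (ENSMUSG00000044791, chromosome 9, 110532597 to 110618633 in GRCm38) stood at 184 and 176 CPM in WT and at 144 and 153 CPM in Setd2-CD4 cre. The means were 180.0 ± 5.14 and 148 ± 6.47 CPM (SD, n = 2 each), a log2 fold change of -0.28 (SE 0.10) that missed the threshold by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0748). It passed under upper-quartile factors (-0.39, edgeR adjusted p = 0.0242), library totals (-0.43, 0.0216) and cyclic loess scaling (-0.44, limma-voom adjusted p = 0.0214). Without Setd2-CD4 cre replicate 24 the log2 fold change was -0.32. The values are sums over the whole gene, so they do not test whether some exons were removed. A separate transcript model inside the span of Setd2 on the same strand, Gm42763 (110543211 to 110545297), named after its values were seen, rose from 5 and 4 counts to 39 and 45 (3.49, SE 0.47, edgeR adjusted p = 0.00219). Lpcat4 (ENSMUSG00000027134, chromosome 2, 112239468 to 112247111) fell from 40.4 ± 1.28 to 20.01 ± 1.46 CPM (SD, n = 2 each), a log2 fold change of -1.01 (SE 0.14, edgeR adjusted p = 0.0026).

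**Figure D1:**
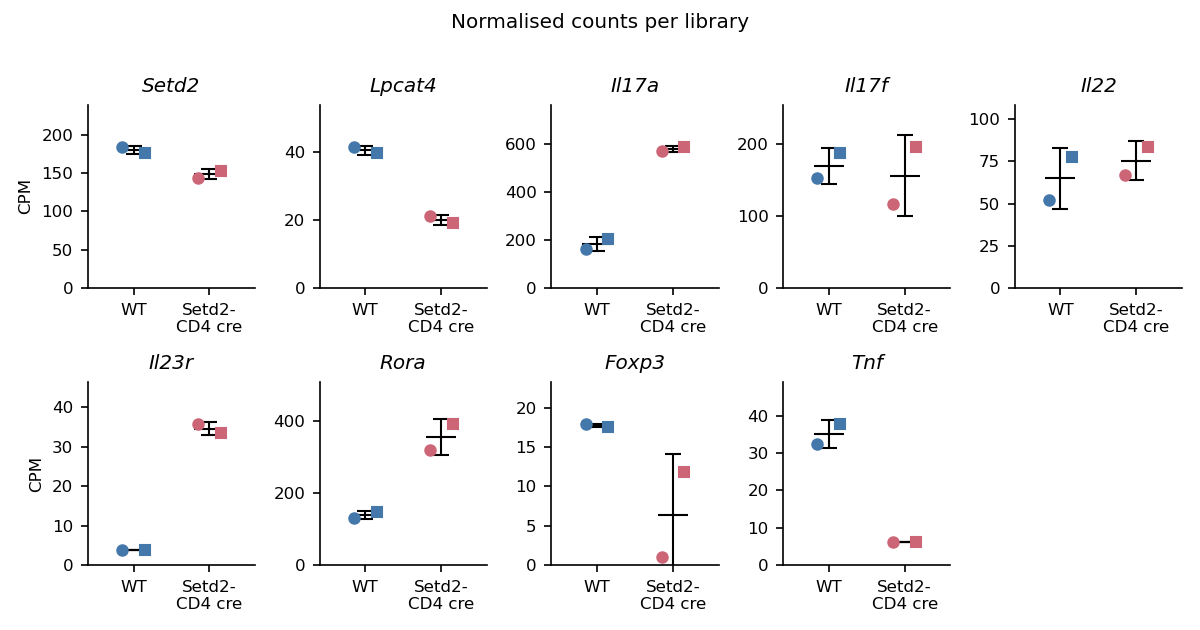
Normalised counts of 9 genes in CPM (vertical axes, from 0) by genotype, with 1 point per library (circles for WT 13 and Setd2-CD4 cre 22, squares for WT 15 and Setd2-CD4 cre 24) and bars at the mean ± SD of 2 libraries. Il17a, Il23r and Rora lay higher in both Setd2-CD4 cre libraries, Lpcat4 and Tnf lay lower, and Foxp3 differed between the Setd2-CD4 cre replicates (0.974 and 11.8 CPM).

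Among 12927 genes tested, 2094 were higher and 1880 lower in Setd2-CD4 cre cultures by edgeR's quasi-likelihood test at an adjusted p of 0.05, and 647 and 714 of these changed at least 2-fold. The genotypes did not overlap for 70.7% of tested genes, where chance gives 33.3% for a single gene. Genes vary together across these libraries, so any shared difference between the groups could raise that share. The largest rises included 3 genes of the Hsp70 chaperone family. Hspa1b went from 5.53 ± 2.86 to 176 ± 21.6 CPM (log2 fold change 4.99, SE 0.35, edgeR adjusted p = 0.00159), and its call was lost without Setd2-CD4 cre replicate 22 (adjusted p = 0.122) or 24 (0.106). Hspa1l (4.63, adjusted p = 0.000695) and Hspa1a (4.56, 0.000695) rose likewise, and reads of Hspa1a and Hspa1b, near-identical copies, may have been split between them. The neutrophil-attracting chemokine genes Cxcl3 (2.36 ± 0.752 to 60.2 ± 21.4 CPM, log2 fold change 4.66, SE 0.35, adjusted p = 0.00116) and Cxcl2 (4.53, adjusted p = 0.0151) were also higher. Cxcl2 rested on 8 and 0 counts in WT against 102 and 51, and DESeq2 gave it an adjusted p of 0.0729. Its log2 fold change ranged from 3.55 to 9.38 when each library was left out.

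Of the other large rises, Fcrla (3.88), Rasgrp3 (3.87), Btk (3.83) and Bcl11a (3.82) are genes of B cell function or development, with edgeR adjusted p-values of 0.0044, 0.00146, 0.0021 and 0.00208. Slc22a4, a carrier gene for organic cations, had a log2 fold change of 3.85 (edgeR adjusted p = 0.000915). Capn11 had 1 and 0 counts in WT and 76 and 47 in Setd2-CD4 cre, a ratio of 152 with a 95% counting interval of 26.9 to 6071. Tmod2 (3.75, edgeR adjusted p = 0.0193) lost its call without WT 13 (adjusted p = 0.129), without WT 15 (0.106) and by limma-trend on log2(FPKM + 1) (0.106). Without Setd2-CD4 cre replicate 24 its log2 fold change was 2.39.

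The largest falls were led by Gpr83, a receptor gene characteristic of regulatory T cells (13.5 ± 2.33 to 0.794 ± 0.434 CPM, log2 fold change -4.06, SE 0.37, edgeR adjusted p = 0.000976), and by Prlr, the prolactin receptor gene (21.5 ± 4.23 to 1.41 ± 0.474 CPM, -3.92, SE 0.30, adjusted p = 0.000695). Tmem136 (-3.75), Prg4 (-3.71), Gipr (-3.04), Rundc3a (-2.97), Stra6 (-2.95) and Sema3b (-2.90) followed, with edgeR adjusted p-values of 0.00171 to 0.00769. Tnf fell from 35.1 ± 3.79 to 6.14 ± 0.00415 CPM (-2.51, SE 0.17, edgeR adjusted p = 0.000584). Mypopos (-2.75), Eme2 (-2.65) and Bcam (-2.48) completed the 12, and Mypopos is an antisense gene whose reads are uncertain without strand.

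Of 23 tested Th17 lineage genes, 10 rose and 4 fell (12 and 4 when adjusted over the list alone), and the list was higher than other genes by camera (adjusted p = 0.000398, and adjusted p = 0.862 with an estimated correlation). Il23r (ENSMUSG00000049093, chromosome 6, 67422932 to 67491855) rose from 3.81 ± 0.00382 to 34.5 ± 1.61 CPM (log2 fold change 3.18, SE 0.18, edgeR adjusted p = 0.000455). Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) rose from 182 ± 27.9 to 578 ± 11.6 CPM (1.67, SE 0.13, adjusted p = 0.000695). Rora, which encodes a nuclear receptor of the Th17 program, rose from 139 ± 10.3 to 355 ± 50.3 CPM (1.35, SE 0.13, adjusted p = 0.00106), and the cytokine gene Il24 rose from 67.1 ± 7.15 to 168 ± 25.9 CPM (1.32, SE 0.14, adjusted p = 0.0013). Il17f stood at 170.0 ± 24.8 and 156 ± 55.9 CPM (-0.12, SE 0.27, edgeR adjusted p = 0.763) and Il22 at 65.1 ± 18.1 and 75.3 ± 11.5 CPM (0.21, SE 0.21, adjusted p = 0.471). Of the pathways annotated in the deposited table, Th17 cell differentiation (23 of 94 genes higher, 15 lower, camera adjusted p = 0.458) and IL-17 signaling (13 of 62 higher, 10 lower, 0.576) did not pass. The 4 list members that fell were Il21 (-0.84), Irf4, Socs3 and Il12rb1, named after their values were seen, and the last 3 lost their calls without WT 13 and without WT 15 (edgeR adjusted p = 0.0609 to 0.374).

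Leaving out Setd2-CD4 cre replicate 24 ended the call of the Th17 lineage list (camera adjusted p = 0.0975), and without WT 13, WT 15 and that replicate the number of members lower was 1, 1 and 7. Il17f had a log2 fold change of 0.03 without WT 15, 0.21 without Setd2-CD4 cre 22 and -0.54 without Setd2-CD4 cre 24. Il22 had -0.05 without WT 13. The B cell markers described further on were higher in the same 2 libraries.

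Among 14 tested genes associated with pathogenic Th17 cells, 5 rose and 2 fell (6 and 2 over the list alone), and the list was higher by camera (adjusted p = 0.0372, and adjusted p = 0.862 with an estimated correlation). Cxcl3, described above, and Il7r, the interleukin 7 receptor gene (0.85, SE 0.11, edgeR adjusted p = 0.00191), rose, while Csf2, the gene for GM-CSF, fell (-2.02, SE 0.38, adjusted p = 0.00785). The list's call was lost without Setd2-CD4 cre 24 (camera adjusted p = 0.0551), and 3, 2 and 8 of its genes were higher without WT 13, WT 15 and Setd2-CD4 cre 24. Of 20 regulatory T cell genes, 5 rose and 6 fell, as over the list alone, and the list did not pass (camera adjusted p = 0.394). Gpr83 fell, Tigit, an inhibitory receptor gene, rose (1.61, SE 0.16, edgeR adjusted p = 0.00118), and Itgae, an integrin gene, fell (-1.36, SE 0.24, adjusted p = 0.0064). Foxp3, the lineage-defining factor gene, stood at 17.9 and 17.6 CPM in WT and at 0.974 and 11.8 CPM in Setd2-CD4 cre (-1.46, SE 1.12, edgeR adjusted p = 0.409). Its log2 fold change was -0.58 without Setd2-CD4 cre 22 and -4.17 without Setd2-CD4 cre 24. Each of these fits left 1 library of that genotype, so neither measured the spread between its libraries.

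Genes of S phase, when DNA is copied, lay lower as a group. Of 24 tested, 19 fell and none rose (20 and 0 over the list alone), with a median log2 fold change of -0.68 (camera adjusted p = 1.22e-08, and adjusted p = 0.862 with an estimated correlation). Pcna, the gene for the replication clamp, fell from 199.97 ± 8.58 to 97.3 ± 9.12 CPM (-1.04, SE 0.12, edgeR adjusted p = 0.00135). The nucleotide synthesis genes Tk1 (-1.15, SE 0.13, adjusted p = 0.00138) and Rrm2 (-1.30, SE 0.15, adjusted p = 0.00159) and the flap endonuclease gene Fen1 (-1.37, SE 0.17, adjusted p = 0.00183) fell likewise. Without WT 15 the number that fell was 7. Of 24 genes of G2 and M phase, 5 rose and 2 fell (5 and 2 over the list alone), with a median of -0.06 (camera adjusted p = 0.980). Among them Birc5 fell (-0.76, edgeR adjusted p = 0.00255) and Ube2c rose (0.53, adjusted p = 0.00822, lost without WT 13 at 0.0818 and without WT 15 at 0.117).

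Of 48 tested genes of the cytosolic ribosome, 22 rose and none fell (24 and 0 over the list alone), with a median log2 fold change of 0.49 (camera adjusted p = 8.44e-06, and adjusted p = 0.987 with an estimated correlation). Rpl24 (0.91, SE 0.14, edgeR adjusted p = 0.00367) and Rps12 (0.85, SE 0.14, adjusted p = 0.00437) had the smallest p-values. The number that rose was 3 without WT 13, 2 without WT 15 and 42 without Setd2-CD4 cre 24, 12 under upper-quartile factors, 10 with library totals and 5 with cyclic loess scaling. The median was 0.27 without Setd2-CD4 cre 22. Of 20 genes of the unfolded protein response of the endoplasmic reticulum, 9 rose and none fell (10 and 1 over the list alone, camera adjusted p = 0.0083, and adjusted p = 0.862 with an estimated correlation). Atf6, which encodes a sensor of that response (0.90, SE 0.11, edgeR adjusted p = 0.00173), and Herpud1, which encodes a protein of the degradation machinery (0.93, SE 0.14, adjusted p = 0.00334), rose. That number was 3 without WT 13 and 2 without WT 15. The sign of the median was the same under all scalings tried for each of the 9 lists past the threshold.

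Markers of other cell types differed between the genotypes. Of 14 tested B cell markers, 11 rose and none fell (12 and 0 over the list alone), with a median log2 fold change of 2.45 (camera adjusted p = 3.91e-11, and adjusted p = 0.862 with an estimated correlation). Ebf1, a factor gene of the B lineage, went from 2.71 ± 0.38 to 21.8 ± 7.81 CPM (3.00, SE 0.31, edgeR adjusted p = 0.00123), and Cr2, a complement receptor gene, from 1.22 ± 0.214 to 9.58 ± 3.95 CPM (2.96, SE 0.40, adjusted p = 0.0023). Ighm, the constant region gene of IgM, went from 191 ± 24.8 to 396 ± 51.4 CPM (1.05, SE 0.14, adjusted p = 0.00213). Ighd (0.42, SE 0.29, edgeR adjusted p = 0.292) and Fcer2a (0.48, SE 0.31, adjusted p = 0.27), named after their values were seen, did not pass. All 14 markers also had counts in WT libraries.

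**Figure D2:**
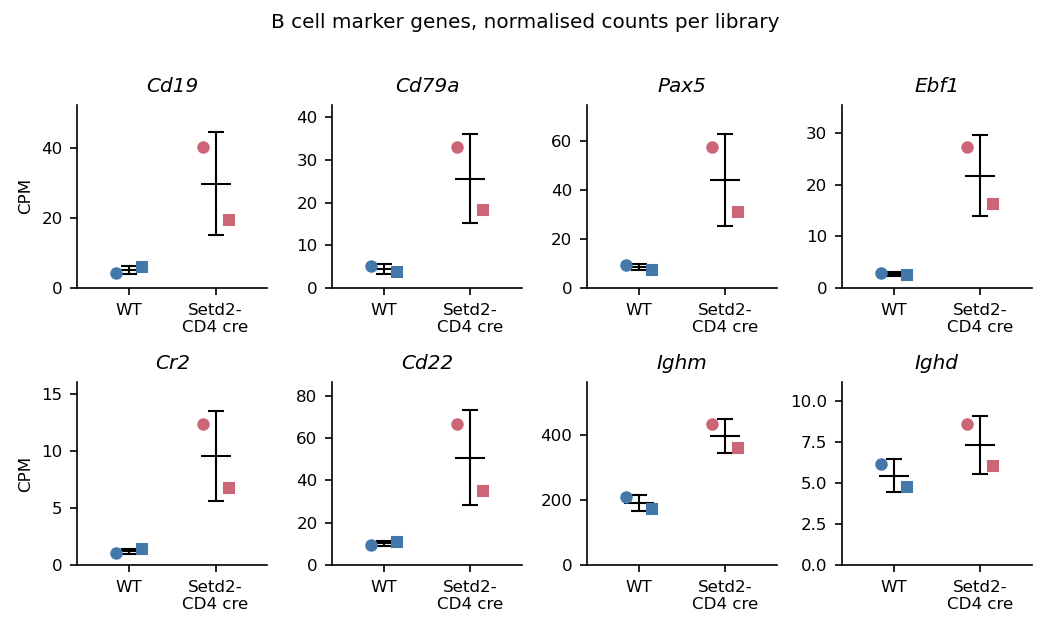
Normalised counts of 8 B cell marker genes in CPM (vertical axes, from 0) by genotype, with 1 point per library (circles for WT 13 and Setd2-CD4 cre 22, squares for WT 15 and Setd2-CD4 cre 24) and bars at the mean ± SD of 2 libraries. Both Setd2-CD4 cre libraries lay above both WT libraries for every gene shown but Ighd, and replicate 22 lay above replicate 24.

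Of 8 dendritic cell markers, 4 rose and none fell (5 and 0 over the list alone, camera adjusted p = 0.0083, and adjusted p = 0.862 with an estimated correlation). H2-Ab1, an MHC class II gene that B cells also express (1.15, SE 0.19, edgeR adjusted p = 0.00464), and Flt3, a cytokine receptor gene (2.28, SE 0.38, adjusted p = 0.00659), had the smallest p-values. The number was 2 without WT 13, 2 without WT 15 and 7 without Setd2-CD4 cre 22. Of 8 CD8 T and NK cell markers, 4 rose and none fell, as over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.872 with an estimated correlation), among them the lectin receptor genes Klrd1 (1.93, SE 0.15, edgeR adjusted p = 0.000695) and Klre1 (1.87, SE 0.32, adjusted p = 0.00523). Cd8a (0.22, SE 0.67, edgeR adjusted p = 0.833), named after its value was seen, did not pass. That list lost its call without Setd2-CD4 cre 22 (camera adjusted p = 0.266), and 2 genes were higher without WT 13 and 2 without WT 15. Of 7 gamma-delta T cell markers, 3 rose and none fell, as over the list alone (camera adjusted p = 0.0208, and adjusted p = 0.862 with an estimated correlation), led by 5830411N06Rik (2.80, SE 0.24, edgeR adjusted p = 0.000742) and Blk, a kinase gene that B cells also express (3.25, SE 0.28, adjusted p = 0.000915). The gamma-delta list lost its call without Setd2-CD4 cre 22 (camera adjusted p = 0.0860), without Setd2-CD4 cre 24 (0.0975) and without Blk (0.236).

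**Figure D3:**
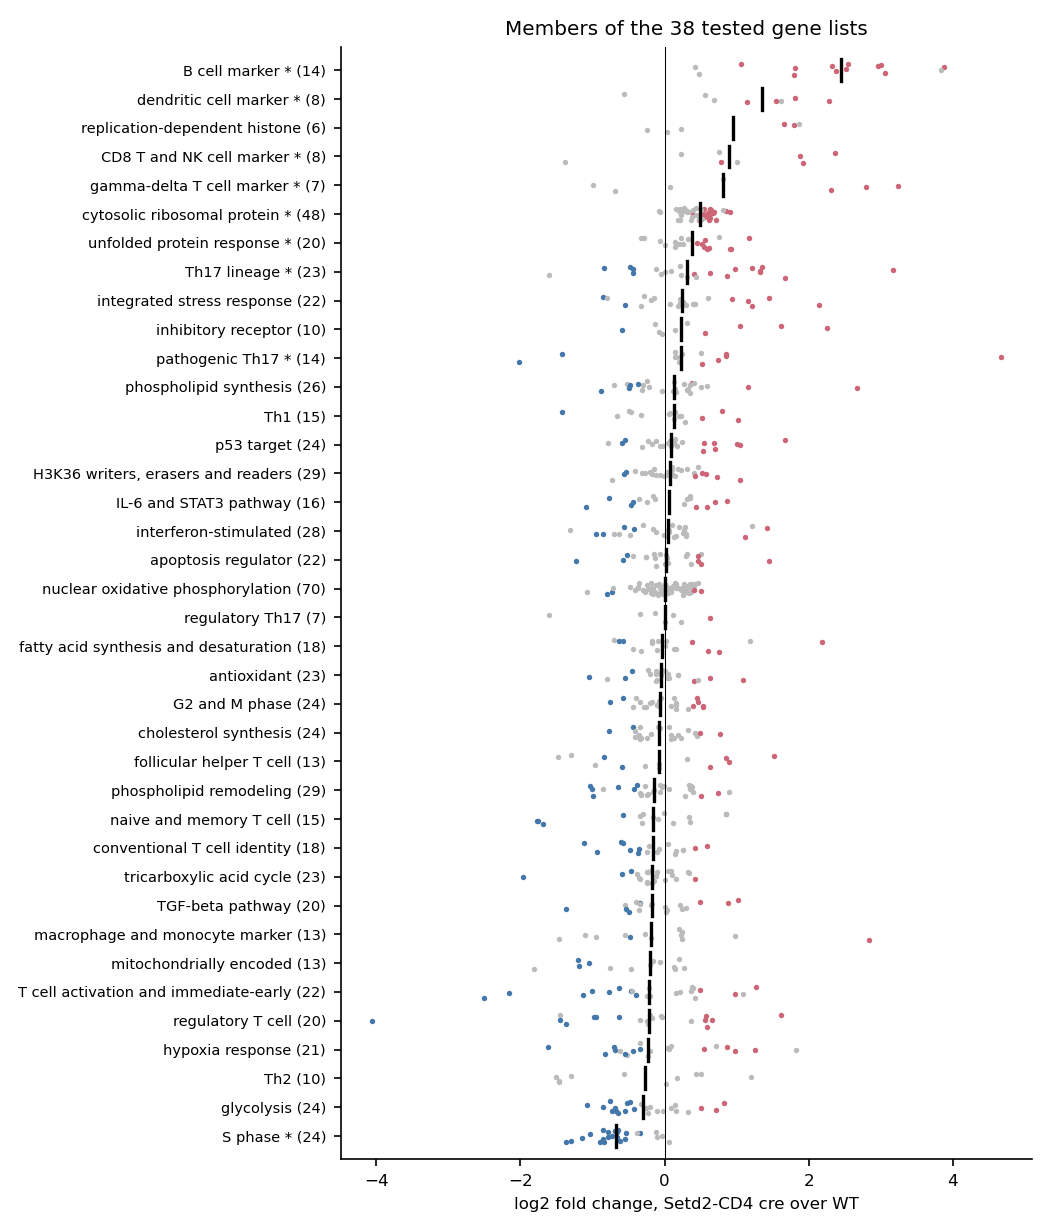
Log2 fold changes (horizontal axis, Setd2-CD4 cre over WT) of the tested members of 38 gene lists, with the number tested in brackets, 1 point per gene (red higher, blue lower, grey not past the threshold), a black bar at each list's median and an asterisk at lists past the camera threshold with the preset correlation. The B cell marker list had the highest median (2.45) and the S phase list the lowest (-0.68).

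Lipid and carbon metabolism lists did not pass as groups. Of 29 phospholipid remodeling genes, 2 rose and 6 fell, as over the list alone (camera adjusted p = 0.675). The list holds Lpcat4, which the title of the series names, so it is not independent of that gene. Besides Lpcat4, Gpcpd1, a glycerophosphodiesterase gene, rose (0.74, SE 0.12, edgeR adjusted p = 0.00449) and Mboat1, an acyltransferase gene, fell (-1.03, SE 0.21, adjusted p = 0.0106). Gpcpd1 lost its call without WT 15 (0.0552), and Mboat1 without WT 13 (0.0866) and WT 15 (0.0742). Of 26 phospholipid synthesis genes, 3 rose and 4 fell, as over the list alone (camera adjusted p = 0.955), with Lpin1, a phosphatidate phosphatase gene, higher (1.16, SE 0.12, edgeR adjusted p = 0.00123). Of 18 genes of fatty acid synthesis and desaturation, 4 rose and 2 fell, as over the list alone (camera adjusted p = 0.713), with a median of -0.04 and a mean of 0.12. The desaturase gene Scd1 rose from 47.1 ± 9.004 to 215 ± 24.96 CPM (2.19, SE 0.16, edgeR adjusted p = 0.000695). Of 24 cholesterol synthesis genes, 2 rose and 2 fell (2 and 1 over the list alone, camera adjusted p = 0.980), with Fdft1 higher (0.77, SE 0.11, edgeR adjusted p = 0.00304). Of 24 glycolysis genes, 3 rose and 11 fell (3 and 12 over the list alone, camera adjusted p = 0.0509), among them Eno1 (-0.76, SE 0.12, edgeR adjusted p = 0.00359) and Pdk1 (-0.68, SE 0.11, adjusted p = 0.00397). Glycolysis passed with library totals (camera adjusted p = 0.0263), without WT 13 (0.0127) and without Setd2-CD4 cre 22 (0.0489), and 4 of its genes were lower without WT 15.

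Of 294 pathways named in the deposited table, 8 passed by camera, and none did with an estimated correlation (smallest adjusted p = 0.981). B cell receptor signaling (24 of 68 genes higher, 4 lower, camera adjusted p = 0.000376) included Rasgrp3 and Btk. Protein processing in endoplasmic reticulum (49 of 150 higher, 13 lower, adjusted p = 0.000909) was led by the chaperone gene Hsph1 (2.17, SE 0.11, edgeR adjusted p = 0.000322), followed by Hspa1a and Hspa1l. Ribosome (36 of 128 higher, 4 lower, camera adjusted p = 0.00119) and antigen processing and presentation (19 of 67 higher, 2 lower, adjusted p = 0.00148) were higher. Antigen processing and presentation was led by Tnf, which fell, and by Hspa1l, Hspa1a and Klrd1, which rose. It thus shares leading genes with protein processing in endoplasmic reticulum. DNA replication (1 of 34 higher, 15 lower, camera adjusted p = 0.00148) and the Fanconi anemia pathway of DNA crosslink repair (2 of 50 higher, 19 lower, adjusted p = 0.00825) were lower. In the latter, Rmi2 (-1.68, SE 0.17, edgeR adjusted p = 0.00114) and Brca2 (-1.33, SE 0.15, adjusted p = 0.00146) fell. Mitophagy (19 of 57 higher, 4 lower, camera adjusted p = 0.0142) was led by the autophagy genes Gabarapl1 (1.47, edgeR adjusted p = 0.000695) and Sqstm1 (1.24, adjusted p = 0.000887), and Legionellosis (14 of 45 higher, 4 lower, camera adjusted p = 0.0281) by Tnf, which fell, and Hspa1a and Hspa1l, which rose.

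The split of calls depended on the processing. Of called genes, 52.7% were higher under TMM, 54.2% with DESeq2's size factors and 52.4% with cyclic loess, against 37.4% under upper-quartile factors and 32.9% with library totals. By limma-trend on FPKM, where the test and the added constant change as well, 31.7 and 32.4% were higher. With 2 libraries per genotype, the counts of calls ranged from 718 to 3068 higher and from 564 to 2903 lower as each library was left out, with the lowest values without WT 15 and the highest without Setd2-CD4 cre 24.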

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

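Cyclic loess scaling, the fit of protein-coding genes alone and the gamma-delta T cell list without Blk were tests chosen after the results were seen. No gene called with TMM scaling was called in the opposite direction under any alternative. Numbers called higher fell to 1247 and 1260 with log2(FPKM + 1) and log2(FPKM + 0.1), and library totals raised those called lower to 2879. An adjusted p under 0.01 left 902 higher and 667 lower, and a change of at least 2-fold left 647 and 714, both fewer by construction. Leaving out each library gave 718 (WT 15) to 3068 (Setd2-CD4 cre 24) higher and 564 to 2903 lower, with 922 and 737 without WT 13, where the lone library of a genotype was assumed to vary like the others. The median of all genes moved to -0.12 under upper-quartile factors and on FPKM + 1 and to -0.16 with library totals and on FPKM + 0.1. Among fits that kept all libraries, Setd2 was past the threshold under upper-quartile factors (-0.39), library totals (-0.43), FPKM + 1 (-0.38), FPKM + 0.1 (-0.43) and cyclic loess (-0.44). Its log2 fold change ranged from -0.32 to -0.23 as each library was left out. Lpcat4 kept its direction and call in every alternative run (-1.17 to -0.93). Camera with an estimated correlation called 0 lists and 0 pathways and fry called 0 lists by direction (32 in either direction), against 9 and 8, and leaving out each library called 7 to 11 lists. In leave-one-out fits, directions of the tallied results turned only where they were not past the threshold. Their ranges were -0.54 to 0.21 for Il17f and -0.052 to 0.52 for Il22. For list medians less the median of all genes they were -0.14 to 0.066 (regulatory Th17), -0.060 to 0.12 (Th1), -0.20 to 0.034 (phospholipid remodeling), -0.052 to 0.087 (fatty acid), -0.11 to 0.028 (cholesterol), -0.11 to 0.22 (nuclear oxidative phosphorylation), -0.066 to 0.097 (antioxidant), -0.23 to 0.58 (integrated stress), -0.068 to 0.12 (interferon), -0.11 to 0.10 (G2 and M phase) and -0.026 to 0.17 (H3K36). Medians of some lists not past the threshold also turned in other fits, such as Th2 with the filter at 5 CPM (0.085 against -0.27) and IL-6 and STAT3 with cyclic loess (-0.13 against 0.07). The cause was not tested for these or for Setd2. With the turned directions above included, single genes other than Setd2 and Lpcat4 kept direction and stayed called or uncalled in 2640 instances, lost the call in 206, gained it in 38 and turned in 3. Lists did so in 222, 24, 7 and 14. Some genes named from pathways or after their values were seen were not in this tally, and of these, among genes not past the threshold, Cd8a (-0.78 without Setd2-CD4 cre 22 against 0.22) and Trdc (-0.62 against 0.07) turned, as did Idi1 without WT 15 (1.14 against -0.24) and Setd2-CD4 cre 24 (0.26), and Malat1 without Setd2-CD4 cre 22 (0.26 against -0.18, edgeR adjusted p = 0.0206). Of 173 named genes, some of which had no call to lose, 47 and 58 lost their call without WT 13 and WT 15, and 8 and 4 without Setd2-CD4 cre 22 and 24. At 11007343 to 12518415 counts, the floor of 3 counts lay at 0.240 to 0.273 CPM, and only 8 of 67 simulated 1.5-fold changes were recovered.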

Other observations

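The tests of a shared source of B-lineage transcripts, mature B cells, gamma-delta T cells, library scaling and genomic DNA were chosen after the results they bear on were seen. The tests of an abundance trend and of host genes were fixed before their results. Several groups of T cell genes beyond those of the report held calls in both directions, as did the tested genes as a whole. Of all 12927 tested genes, 2094 were called higher and 1880 lower (30.7% in all), so calls near that share do not set a list apart. Of 15 genes of naive and memory T cells, 1 rose and 4 fell, as over the list alone (camera adjusted p = 0.126). The quiescence gene Klf2 (-1.76, edgeR adjusted p = 0.00106) and the surface marker gene Ly6c1 (-1.69, 0.000935) fell, and Il7r rose. Of 22 activation and immediate-early genes, 3 rose and 8 fell (5 and 8 over the list alone, camera adjusted p = 0.403), with Tnf lower and Nr4a3 (1.27, edgeR adjusted p = 0.000915) and Jun (0.97, 0.00177) higher. Of 18 conventional T cell identity genes, 2 rose and 7 fell, as over the list alone (camera adjusted p = 0.186), among them the T cell receptor complex gene Cd3g (-0.94, edgeR adjusted p = 0.00173). Of 13 follicular helper genes, 4 rose and 2 fell (4 and 3 over the list alone, camera adjusted p = 0.980). The repressor gene Bcl6 rose (1.51, edgeR adjusted p = 0.00142) and the inhibitory receptor gene Btla fell (-0.59, 0.00736, lost without WT 13 at 0.0695). Of 15 Th1 genes, 3 rose and 1 fell, as over the list alone (camera adjusted p = 0.713), with Runx3 higher (1.02, edgeR adjusted p = 0.00123). Of 10 Th2 genes none passed by edgeR, over all genes or the list alone, or by camera as a list (adjusted p = 0.713), with the smallest p for the cytokine gene Il13 (-1.47, edgeR adjusted p = 0.0518). Of 7 regulatory Th17 genes 1 rose, Ahr (0.63, edgeR adjusted p = 0.00666, lost without WT 13 at 0.0667 and WT 15 at 0.0547), and none fell, as over the list alone (camera adjusted p = 0.980). Of 10 inhibitory receptor genes, 4 rose and 1 fell, as over the list alone (camera adjusted p = 0.204), with Tigit higher and Btla lower. Of 20 TGF-beta pathway genes, 3 rose and 4 fell, as over the list alone (camera adjusted p = 0.955), with the pathway repressor genes Tgif1 (1.02, edgeR adjusted p = 0.00143) and Skil (0.88, 0.00213) higher. Of 16 IL-6 and STAT3 genes, 4 rose and 4 fell (6 and 4 over the list alone, camera adjusted p = 0.964), with Stat3 higher (0.86, edgeR adjusted p = 0.002) and Socs1, an inhibitor of cytokine signaling, lower (-1.09, 0.00218).

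Stress and energy genes also held calls in both directions, to be read against the 30.7% of all tested genes that were called. Of 22 integrated stress response genes, 5 rose and 2 fell, as over the list alone (camera adjusted p = 0.126, 0.0107 without WT 15 and 0.00176 without Setd2-CD4 cre 24). Its central factor gene Atf4 rose (1.45, edgeR adjusted p = 0.00106), and Ppp1r15a rose (2.15, 0.0021) but was not called without Setd2-CD4 cre 22 (0.153) or 24 (0.145). Of 24 p53 target genes, 7 rose and 2 fell, as over the list alone (camera adjusted p = 0.336), among them Mdm2 (0.71, edgeR adjusted p = 0.00288) and Gadd45a (1.68, 0.00333). Of 22 apoptosis regulators, 4 rose and 3 fell, as over the list alone (camera adjusted p = 0.955), with Birc2 higher (1.45, edgeR adjusted p = 0.00106) and Bcl2 lower (-0.58, 0.00795, lost without WT 13 at 0.0597 and WT 15 at 0.0939). Of 28 interferon-stimulated genes, 2 rose and 4 fell, as over the list alone (camera adjusted p = 0.955), with Usp18 higher (1.12, edgeR adjusted p = 0.00248) and Ddx58 lower (-0.95, 0.00274). Of 21 hypoxia genes, 4 rose and 7 fell (6 and 7 over the list alone, camera adjusted p = 0.770), with Egln3 lower (-1.61, edgeR adjusted p = 0.000706) and Mxi1 higher (0.97, 0.00146). Of 23 antioxidant genes, 3 rose and 3 fell, as over the list alone (camera adjusted p = 0.980). The glutathione synthesis genes Gss (1.10, edgeR adjusted p = 0.00135) and Gclm (-1.04, 0.00671, lost without WT 15 at 0.0586) moved apart. Of 13 mitochondrially encoded genes, 3 fell and none rose, as over the list alone (camera adjusted p = 0.0886), with mt-Nd5 lower (-1.20, edgeR adjusted p = 0.00139). The mt-Cytb fall (-1.05, edgeR adjusted p = 0.00804) was lost without Setd2-CD4 cre 22 (0.155) or 24 (0.247). That list passed without WT 13 (camera adjusted p = 0.00463) and without Setd2-CD4 cre 22 (0.00708). Of 70 nuclear oxidative phosphorylation genes, 2 rose and 2 fell (0 and 0 over the list alone, camera adjusted p = 0.980), and of 23 tricarboxylic acid cycle genes, 1 rose and 3 fell (0 and 2 over the list alone, 0.302), with the pyruvate carboxylase gene Pcx lower (-1.97, edgeR adjusted p = 0.00177). Of 29 writers, erasers and readers of H3K36 methylation, 5 rose and 2 fell, as over the list alone (camera adjusted p = 0.713), with the chromodomain gene Morf4l1 (0.73, edgeR adjusted p = 0.00403, lost without WT 15 at 0.0541) and Morf4l2 (1.05, 0.00167) higher. Of 6 tested replication-dependent histone genes 2 rose and none fell (3 and 0 over the list alone, camera adjusted p = 0.286). Of 13 macrophage and monocyte markers, 1 rose, Tyrobp (2.83, edgeR adjusted p = 0.00185), and 1 fell, Cst3 (-0.47, edgeR adjusted p = 0.0490, lost without WT 13 at 0.193, WT 15 at 0.172 and Setd2-CD4 cre 22 at 0.0778), against 1 and 0 over the list alone (median -0.19, camera adjusted p = 0.980). The macrophage genes Adgre1 (8 and 8 counts in WT) and C1qa (5 and 9), named after their values were seen, had 0 in both Setd2-CD4 cre libraries. Too few members were tested for neutrophil (2 tested, none past the threshold by edgeR), erythroid (0 tested), stromal (4 tested, 2 higher, none lower) and sex-linked lists (4 tested, 3 higher, none lower). Ddx3y, on the Y chromosome, was among the last (0.85, edgeR adjusted p = 0.0144, lost without WT 15 at 0.0678, Setd2-CD4 cre 22 at 0.375 and Setd2-CD4 cre 24 at 0.339), and Xist had at most 4 counts in any library. Among genes that stood apart between replicates, besides Foxp3, were mt-Nd4l (1 count in Setd2-CD4 cre 22 and 1220 in 24), Cd5l (1 and 51), Lyz2 (4 and 42), Malat1 (739 and 1548 CPM, with 1308 and 1289 in WT) and Idi1 (298 and 1254 counts in WT), all named after their values were seen.

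The rises of B cell markers over WT were 2.22 times as large in Setd2-CD4 cre 22 as in 24 (quartiles 1.86 to 2.66 over 14 markers). That ratio was 1.16 (0.855 to 1.602) for the other 2083 genes called higher. A shared source larger in 22 would give this contrast, but that account was written after the marker values were seen. The other genes were chosen by their calls, which favor agreement between replicates, so the contrast does not test for a shared source. Mature B cells carried into the cultures, whose isolation step is not given in the sources used here, cannot be told apart from B-lineage transcription in T cells, and the rise of Cd74, abundant in B cells, at 2.15 times that of Pax5, decides nothing, as the bounds of 1 and 10 were set after it was seen. Other tests were tried first and set aside, in which Ighd and Fcer2a, genes of resting follicular B cells, had a mean log2 fold change of 0.45 (SE 0.213) against a median of 2.53 for the other markers, which speaks only to such cells and leaves activated B cells open. Igkc, among the most abundant B cell transcripts, rose by 0.607 and 0.665 CPM per CPM of Pax5 in 22 and 24, where no B cell library was analysed here to say what ratio to require and reads across rearranged junctions may be lost. The genotype stays open as a biological explanation and was not tested apart from such cells.

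The rise of Il17a and Il23r may have come from gamma-delta T cells, which also make interleukin 17. The 7 tested markers of these cells split, since Trdc and the 3 tested Tcrg-C genes, for the constant regions of their receptor, had a median log2 fold change of -0.31 (SD 0.811, 4 genes) with 6 to 68 counts per library, and Blk (3.25), 5830411N06Rik (2.80) and Cd163l1 (2.31, lost without WT 15 at an edgeR adjusted p of 0.0923) rose. The receptor genes do not show more such cells, but at these counts they exclude little, and the explanation stays open. Library scaling as the source is argued against by log2 fold changes for Il17a of at least 1.51 (SE 0.137) with DESeq2's size factors, upper-quartile factors and library totals, and of 1.47 with cyclic loess. An effect of genotype on Il17a and Il23r in CD4+ T cells remains a hypothesis, found and examined on the same 4 libraries. Neither CD8 T and NK cells, of whose 8 tested markers 4 rose and none fell, nor other cells were examined as a source of these rises.

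Transcript models inside protein-coding genes and on their strand tended to be higher in Setd2-CD4 cre cultures (sense-intronic class, 9 of 39 higher and 4 lower, median log2 fold change 0.55, and 159 unconfirmed models, class TEC, median 0.71), while TEC models inside genes on the opposite strand only (9, median -0.99) or outside genes (68, median -0.76), lincRNA (17 of 206 higher, 51 lower, median -0.62) and antisense models (9 of 182 higher, 36 lower, median -0.69) were lower. A trend of fold change with abundance is argued against by matched lists of protein-coding genes, of which 6 in 10000 reached the sense-intronic median, and genomic DNA by the falls of lincRNA and antisense models (the higher median was -0.62). Change of the host gene is argued against by 196 models inside genes, 159 of class TEC and 37 sense-intronic. These exceeded their hosts on the same strand by a median of 0.54 (SE 0.0644), 145 of them lying above the host. That SE treats the models as independent, though all come from the same libraries and some share a host. It does not measure the spread between libraries. Against the median of its class, the abundant model Gm26917, annotated as a lincRNA, rose (40.7 to 308 CPM, log2 fold change 2.92, edgeR adjusted p = 0.00211, named after its values were seen). What its reads came from was not examined, so it bears on none of these explanations. For the models inside genes, unspliced RNA and transcription started within genes are both open. A role of the Setd2-CD4 cre genotype remains a hypothesis that these data do not test, and stranded reads, with those across splice junctions told apart from those within introns, could decide between the open explanations.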
